A study of Strongylocentrotus purpuratus with 6 samples.

How the data were processed

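Total RNA from ovary, egg, 32-cell embryo, blastula, gastrula and pluteus of *Strongylocentrotus purpuratus* was run on a urea gel from which RNA of 18 to 40 nt was cut, per the labels' protocols. Per the same protocols, libraries were made with an Illumina small RNA kit that needs a 5′ monophosphate, and were read on a Genome Analyzer 2. The deposited files give read counts, 1 whole number per distinct sequence of 18 to 36 nt, not normalised. How the 3′ adapter was removed and identical reads were merged is not given in the sources used here. Reads of 34 to 36 nt made up from 25.9% (32-cell) to 44.9% (egg) of a library, and whether each is an untrimmed read or a longer insert was not resolved. Reads holding library adapter made up from 1.02% (32-cell) to 15.4% (egg) of a library. The libraries held between 4057827 and 8777792 reads, 43368040 in all, and every stage had 1 library. Identical reads may be PCR copies, since no molecular identifiers were used.

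No genome was used here. Neither the matching of reads to the genome, nor the check that added end bases are absent from the genome, nor the other hairpin arms could be run. The table of gene names of assembly Spur_5.0 was not used. The mature sequences of 40 miRNAs and 11 control miRNAs of human, fly and plant were written from general knowledge before the data were examined. For each, the most abundant sequence of 20 to 24 nt with the same nt 2 to 8 and at most 3 mismatches over nt 1 to 20 was taken as its form here. Other forms meeting these limits with at least 5% of the reads of the first were added under the same name, giving 48 forms. miR-92 and miR-7 then have 3 forms each, and let-7 and miR-29 each have 2, which may come from separate genes. After the data were seen, the sequences of 3 miRNAs were added: miR-2001, miR-242, and miR-2011 with its start moved by 1 nt. In all 42 miRNAs were searched. A read of 18 to 26 nt counted for a miRNA when its first 18 nt equalled those of a form.

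The share of miRNA reads and of length classes was taken over all reads, with exact Clopper-Pearson 95% intervals. For each of the 5 comparisons, miRNA RPM (reads scaled to a common total of miRNA reads) were set against each other as a ratio with an exact conditional binomial 95% interval. A miRNA was called higher or lower when it had at least 30 reads in the larger library, a ratio of at least 2 or at most 0.5 and an interval that excluded 1. These calls compare 2 libraries, not stages, since variation between cultures or animals was not measured. No p-value is given. Because miR-31 and miR-2012 make up most miRNA reads, a change in either moves the ratio of every other miRNA. Lists of miRNAs were fixed by name before the data were examined: let-7 complex, muscle, neural and neurosecretory, sensory cluster, ciliated and gut epithelium, shared with protostomes and germline, echinoderm or ambulacrarian, and 4 miRNAs known to have been studied by the authors. The echinoderm list was fixed as miR-2001 to miR-2013, but only 10 members of that range were given a sequence. The other names were not searched, so the counts and percentiles of this list cover those 10. The sequences used for miR-2001, miR-2011 and miR-242 came later, so the counts and percentiles of the echinoderm list and of the list shared with protostomes rest in part on a choice made after the data were seen. The median log2 ratio of a list with 3 or more measured members was placed among 10000 random lists of the same size, drawn within 3 classes of abundance. With so few miRNAs these percentiles describe the libraries and test nothing.

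The text names up to 5 miRNAs with the highest and up to 5 with the lowest ratio among the called ones of each comparison. It also names the 5 most abundant miRNAs of each library, the members of the lists and the kind of the 3 most abundant other sequences of each library. This rule was fixed before the data were examined. Alternatives chosen at the same time were RPM of all reads, TMM factors, median-of-ratios factors, no minimum of reads (with 0.5 read added), a minimum of 100 reads and full mature sequences. Further ones were a match over 16 nt with a start shifted by up to 1 nt, other denominators, other size limits and counts of distinct sequences. Alternatives added after the data were seen were reads of any length, the list without the 3 later miRNAs, the egg library in place of the 32-cell library, and other minimums and summaries for 3′ ends.

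The share of reads with extra A or U was taken per miRNA as the canonical sequence (its commonest 3′ end, each library weighted alike) followed by 1 to 4 A or U. Only reads of the first form of a miRNA entered this share, which for miR-92 were 9783 of 17823 reads in egg. Fragments of rRNA, used as a check of size and of end bases, were reads of up to 31 nt whose first 16 nt lie in 6 conserved rRNA segments. These segments were chosen after the data were seen.

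The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors. The interval and the calling rule were tested on simulated data of 200 features in a pair of libraries. The 95% interval held the true ratio in 95.8% of cases. The rule called 100% of features with a true ratio of 4-fold or more, 98.8% of those between 2.3-fold and 4-fold, and 0.0625% of those under 1.5-fold.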

Results

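Small RNA was sequenced from 6 developmental stages of the purple sea urchin *Strongylocentrotus purpuratus*, an echinoderm whose embryos are used to study early development. The stages were ovary, egg, 32-cell embryo (5 hours post fertilisation), blastula (24 hours), gastrula (48 hours) and pluteus larva (72 hours). Each stage had 1 library, so no difference below has a replicate check, no p-value is given, and the 95% intervals cover counting error only. The libraries held 6970109 reads (ovary), 4057827 (egg), 7918298 (32-cell), 7392649 (blastula), 8251365 (gastrula) and 8777792 (pluteus). A sequence with 0 reads could have had a level of up to 0.739 RPM (reads scaled to a common total of all reads; the limit is 3 reads) in the egg library, the smallest, and up to 0.342 in the pluteus library. The question posed by the series is how small RNA expression changes through early development.

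Reads of a listed microRNA (miRNA, a regulatory RNA of about 22 nt) made up 3.77% of the ovary library (Clopper-Pearson 95% interval 3.75 to 3.78), 10.8% of the egg library (10.8 to 10.9) and 1.17% of the 32-cell library (1.17 to 1.18). The share was 6.27% in blastula (6.25 to 6.29), 11.8% in gastrula (11.8 to 11.8) and 10.3% in pluteus (10.3 to 10.3). Reads of piRNA size (25 to 31 nt) were most frequent in 32-cell, where miRNA reads were least frequent. They formed 29.8% of egg reads, 69.7% of 32-cell reads, 58.7% of blastula reads, 42.6% of gastrula reads and 40.2% of pluteus reads, beside 41.3% in ovary. Reads of 20 to 24 nt, the size of miRNAs, formed 13.3% in ovary, 21.5% in egg, 3.82% in 32-cell, 11.5% in blastula, 20.7% in gastrula and 20.2% in pluteus. Per 100 reads of piRNA size there were 36.4 miRNA reads in egg and 1.69 in 32-cell. Reads of 34 to 36 nt took between 25.9% (32-cell) and 44.9% (egg) of a library, and they count in the denominator of these shares.

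**Figure D1:**
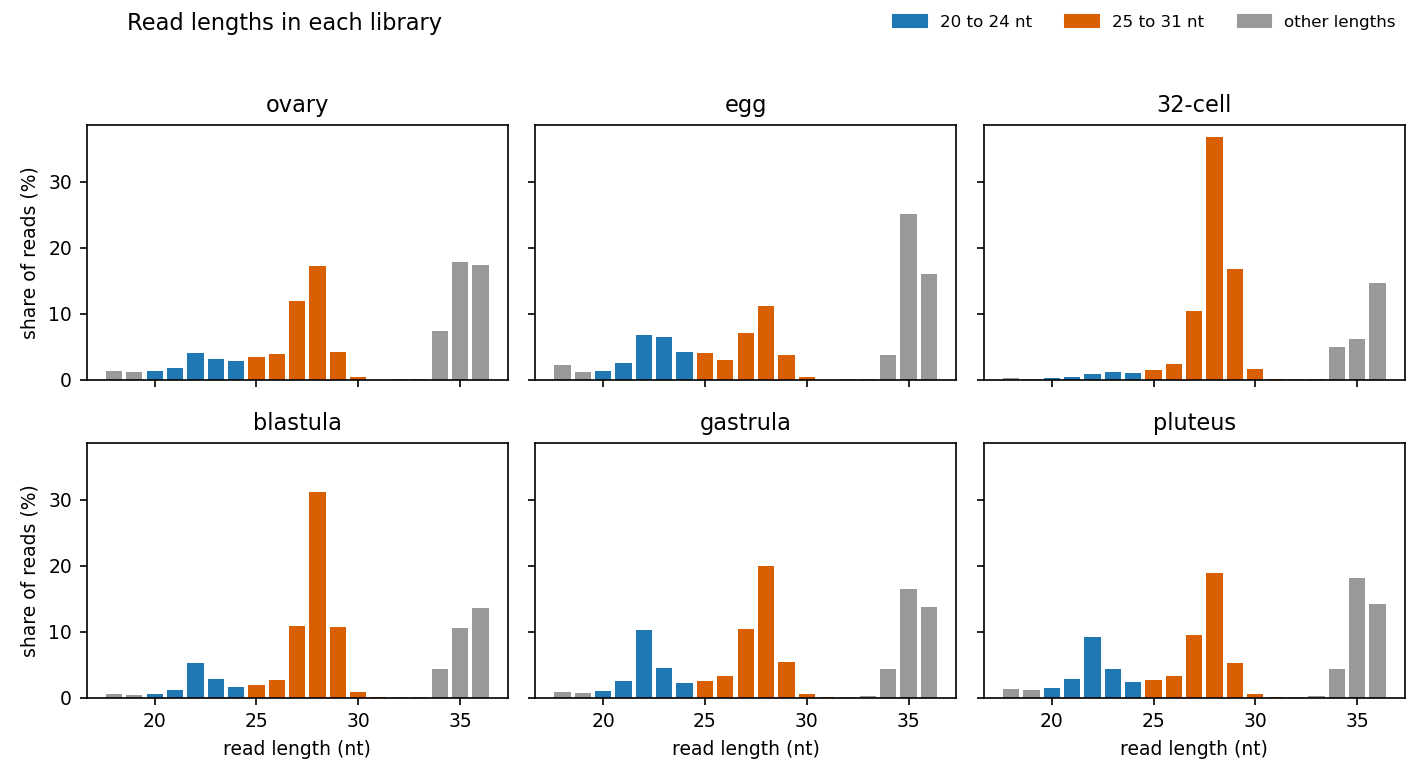
Share of reads (vertical axis, %) at each read length from 18 to 36 nt (horizontal axis), 1 panel per library, with 20 to 24 nt in blue, 25 to 31 nt in orange and other lengths in grey. The 32-cell library has 69.7% of its reads in orange and 3.82% in blue, and the egg library 29.8% and 21.5%.

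The piRNA-size reads carried the sequence features of PIWI-interacting RNAs, the germline small RNAs that silence transposons. With miRNA reads and reads holding an N left out, 80.1% began with U in ovary, 83.0% in egg, 84.5% in 32-cell, 82.2% in blastula, 79.3% in gastrula and 75.4% in pluteus. Among those that did not begin with U, A stood at position 10, the mark of piRNAs made by the ping-pong cycle, in 42.9% in ovary, 44.7% in egg, 43.1% in 32-cell, 51.1% in blastula, 52.8% in gastrula and 49.9% in pluteus. At positions 9 and 11 of the same reads, A stood in 24.4% and 26.6% in ovary and in 26.5% and 28.7% in gastrula. The commonest length among reads of piRNA size was 28 nt in every library. The number of 29 nt reads per 27 nt read was 0.354 in ovary, 0.545 in egg, 1.61 in 32-cell, 0.999 in blastula, 0.521 in gastrula and 0.554 in pluteus. The intervals of these base shares were each narrower than 1 percentage point.

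The same pair of miRNAs led every library. miR-31 (AGGCAAGATGTTGGCATAGCTG) and miR-2012 (TAGTACTGGCATATGGACATTG, an echinoderm miRNA) together made up 63.0% of miRNA reads in ovary, 85.0% in egg, 88.3% in 32-cell, 93.6% in blastula, 83.4% in gastrula and 81.2% in pluteus. miR-2012 was the most abundant miRNA in egg, with 44.0% of miRNA reads (43.8 to 44.1), and miR-31 in the other 5 libraries, with 34.6% in ovary and 67.1% in blastula. Next in abundance were miR-1 (16.7%) and miR-71 (8.51%) in ovary, miR-71 (5.32%) and miR-92 (4.05%) in egg, and miR-92 (3.62%) and miR-71 (3.27%) in 32-cell. miR-1 and miR-184 took these places in blastula (1.21% and 1.07%), gastrula (8.42% and 1.98%) and pluteus (9.59% and 3.37%). The fifth was miR-92 in ovary (2.97%), blastula (1.05%) and pluteus (1.52%), miR-29 in egg (1.47%) and 32-cell (1.46%), and miR-219 in gastrula (1.54%). At least 30 reads were found for 24 miRNAs in ovary, 23 in egg, 16 in 32-cell, 23 in blastula, 26 in gastrula and 26 in pluteus.

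**Figure D2:**
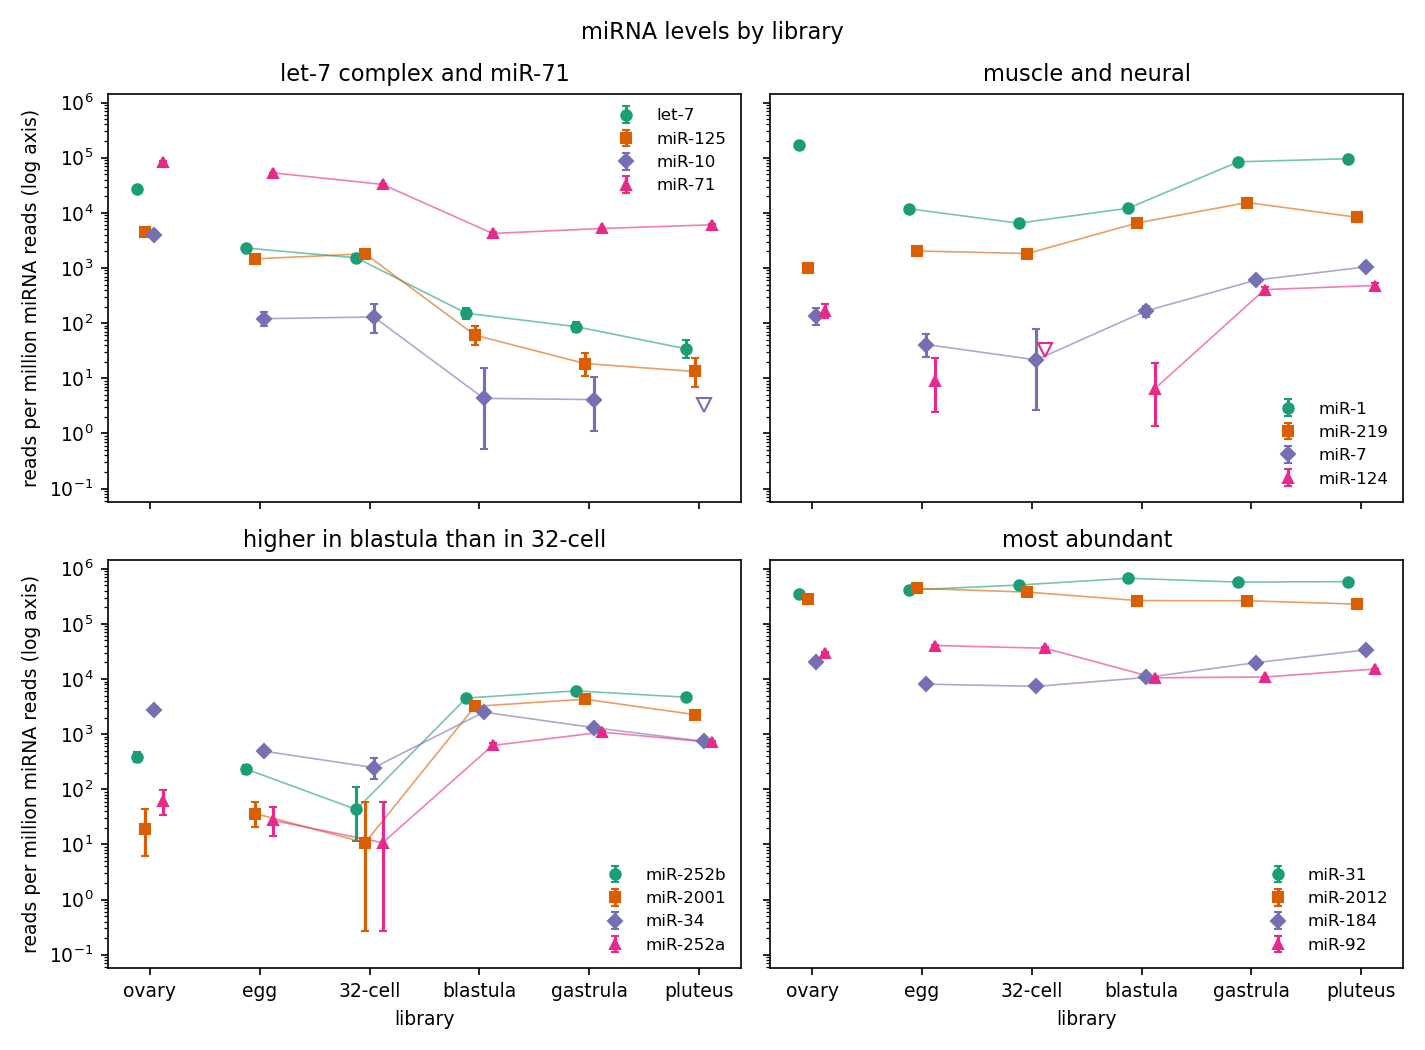
Level in miRNA RPM (reads scaled to a common total of miRNA reads; vertical axis, logarithmic) of 16 miRNAs in the 6 libraries (horizontal axis), with exact 95% counting intervals as bars, lines joining egg to pluteus, and open triangles at the level of 3 reads for a miRNA with 0 reads. let-7 goes from 27496 in ovary to 34.3 in pluteus, and miR-252b from 43.0 in 32-cell to 4516 in blastula.

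The egg is made in the ovary, and the first comparison sets the egg against it. The ovary held more of the list named let-7 complex, here the timing regulator let-7, miR-125 and miR-10, and more of the muscle miRNA miR-1. The list took miR-10 for its whole family, so values of miR-10 itself are no evidence on the let-7 complex as a gene cluster. Relative to all miRNA reads, miR-10 was 32.2-fold lower in egg (24.4 to 43.3), let-7 (TGAGGTAGTAGGTTGTATAGTT) 12-fold lower (11.2 to 12.8) and miR-125 3.14-fold lower (2.85 to 3.46). miR-1 (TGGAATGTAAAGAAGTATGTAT) was 14.1-fold lower in egg (13.7 to 14.5), from 167220 to 11846 miRNA RPM. miR-124, a neuronal miRNA, was 18.4-fold lower on 44 and 4 reads (6.71 to 70.6), and miR-2002 was 10.5-fold lower (8.30 to 13.5). Higher in egg were miR-29 at 2.74-fold (2.59 to 2.91), miR-96, a miRNA of sensory cells in vertebrates, at 2.24-fold (1.37 to 3.83), and miR-219 at 2.06-fold (1.79 to 2.37).

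Of the 26 miRNAs with 30 reads in either of these libraries, 3 were higher in egg, 12 lower and 11 neither, by the rule of a 2-fold ratio with an interval excluding 1. In the list named let-7 complex, miR-10 included, 3 of 3 members were lower (2 of 3 on the RPM scale of all reads, where miR-125 was 1.09-fold lower and not called). The median log2 ratio of -3.58 stood at the 4.27th percentile of random lists matched on abundance. The muscle list had 1 measured member, miR-1, which was lower. In the neural list miR-219 was higher, and miR-7 (3.26-fold) and miR-124 were lower. The sensory list had miR-96 alone, which was higher. Among the 6 measured members of the epithelial list miR-29 was higher, miR-34 (5.69-fold) and miR-210 (7.26-fold) were lower and 3 were neither, with a median at the 73.6th percentile. In the list shared with protostomes 1 of 5 was lower, miR-184 (2.49-fold, but higher on the RPM scale of all reads), with a median at the 37.8th percentile. In the echinoderm list 3 of 7 were lower, miR-2002, miR-2004 (3.9-fold) and miR-2011 (2.71-fold, but higher on the RPM scale of all reads), with a median at the 86.9th percentile. Of miR-1, miR-31, miR-71 and miR-2012, the 4 miRNAs the study worked on and therefore no independent list, miR-1 was lower and 3 were neither, with a median at the 56.5th percentile.

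The direction of the ovary and egg calls as a set depended on the scale. On the RPM scale of all reads each log2 ratio moves up by 1.53, giving 12 miRNAs higher in egg and 6 lower, and there, of the miRNAs called lower, miR-184 and miR-2011 turned to the higher side without being called. On that scale miR-34 (1.98-fold lower), miR-2004 (1.35-fold), miR-7 (1.13-fold) and miR-125 (1.09-fold) also lost their calls, and miR-10, miR-124, miR-1, let-7, miR-2002 and miR-210 were still called lower. With TMM factors miR-96 (log2 ratio 0.74) and miR-219 (0.62) lost their calls, and miR-219 also lost it with full mature sequences (0.31). The split was 1 higher and 14 lower with TMM factors and 8 higher and 9 lower with median-of-ratios factors.

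From egg to the 32-cell embryo, the cleavage stage, the mix of miRNAs changed little. miR-252b, which is shared with protostomes, was 5.39-fold lower in 32-cell on 102 and 4 reads (2.04 to 20.2), and it was the single call among 23 measured miRNAs. With full mature sequences its log2 ratio was -1.30 and it was not called, which left no call in this comparison. miR-34 stood at a ratio of 0.504 (0.313 to 0.776), miR-1 at 0.548 (0.503 to 0.597), miR-71 (TGAAAGACATGGGTAGTGAGATT) at 0.615 (0.592 to 0.639) and miR-2010 at 1.66 (1.31 to 2.09), all inside the 2-fold limits. miR-31 had a ratio of 1.23 (1.22 to 1.25), miR-2012 of 0.858 (0.848 to 0.867), let-7 of 0.665 (0.554 to 0.793) and miR-29 of 0.992 (0.935 to 1.05). The 32-cell library held 92968 miRNA reads against 439975 in egg, so that miRNAs with few reads are poorly measured in it.

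By list, the let-7 complex had 3 members inside the limits (median at the 82.8th percentile) and the epithelial list 5 (75.8th). The echinoderm list had 7 inside the limits (21.6th), the list shared with protostomes 4 and miR-252b lower (67.7th), and the 4 miRNAs of the study all 4 (5.65th). miR-1, miR-219 and miR-96, the measured members of the muscle, neural and sensory lists, were inside them too. The scale decides this comparison. On the RPM scale of all reads each log2 ratio falls by 3.21, and 23 of 23 miRNAs were then lower in 32-cell, from 5.57-fold for miR-2010 to 49.8-fold for miR-252b. With TMM factors 0 were higher and 1 lower, and with median-of-ratios factors 0 and 3.

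Between the 32-cell embryo and the blastula a set led by miR-2001 and miR-252b rose, while miR-71 and the 2 measured of 3 members of the let-7 complex were lower as a part of the miRNA pool. miR-2001 went from 1 read to 1480, a ratio of 297 (53.2 to 11735), and miR-252b from 4 reads to 2093, a ratio of 105 (40.9 to 386). miR-252a rose 58.0-fold (10.3 to 2298), miR-34 rose 10.1-fold (6.72 to 16) and miR-7, a miRNA of neurosecretory cells, rose 7.72-fold on 2 and 77 reads (2.07 to 64.9). Lower in blastula were miR-125 by 29.9-fold (20.0 to 46.4), miR-2013 by 18.8-fold (13.4 to 26.9), let-7 by 10.1-fold (7.54 to 13.7), miR-71 by 7.74-fold (7.31 to 8.19) and miR-2004 by 6.77-fold (4.40 to 10.5).

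Of 24 measured miRNAs 9 were higher in blastula, 10 lower and 5 neither. In the neural list 2 of 2 were higher, miR-7 and miR-219 (3.58-fold), and in the sensory list miR-96 was higher (3.01-fold). In the let-7 complex 2 of 2 measured members were lower (on the RPM scale of all reads miR-125 alone was called), and miR-10, with 12 and 2 reads, was not tested. The epithelial list had miR-34 higher and 3 lower, namely miR-29 (6.18-fold), miR-92 (3.44-fold) and miR-200 (4.56-fold), the last pair turning to higher values on the RPM scale of all reads, with a median at the 15.4th percentile. The list shared with protostomes had miR-252a, miR-252b and miR-242 (3.32-fold) higher, miR-71 lower and 2 neither, with a median at the 90.8th percentile. The echinoderm list had miR-2001 and miR-2002 (3.41-fold) higher, 4 lower, namely miR-2004, miR-2007 (2.32-fold, but higher on the RPM scale of all reads), miR-2010 (6.69-fold) and miR-2013, and 2 neither, with a median at the 27.4th percentile. In the muscle list miR-1 had a ratio of 1.87 (1.72 to 2.04) and was not called. Of the 4 miRNAs of the study miR-71 was lower and 3 were neither, with a median at the 81.7th percentile.

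The 9 higher miRNAs of this comparison were called on each scale run, and the lower ones depended on the scale. On the RPM scale of all reads each log2 ratio rises by 2.42, and 15 miRNAs were higher and 2 lower, miR-125 (5.60-fold) and miR-2013 (3.52-fold). On that scale let-7 was 1.89-fold lower, miR-71 1.45-fold lower and miR-29 1.16-fold lower, and of the 10 lower miRNAs miR-92, miR-200 and miR-2007 turned to higher values, of which miR-2007 was called higher (2.3-fold). The split was 12 higher and 9 lower with TMM factors, and 12 and 9 with median-of-ratios factors. With the egg library in place of the 32-cell library, a comparison chosen after the low miRNA share of the 32-cell library was seen, 9 miRNAs were higher in blastula and 13 lower, and these included the 9 higher and 10 lower named above. The ratio of blastula to egg was 87.8 for miR-2001 and 19.5 for miR-252b, and let-7 was 15.2-fold and miR-71 12.6-fold lower in blastula than in egg.

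From blastula to gastrula, when the gut forms and neurons and muscle precursors arise, miR-1, the measured miRNA of the muscle list, and the 4 measured of 7 neural miRNAs rose. miR-124 rose 62.6-fold on 3 and 395 reads (21.3 to 305), miR-9, another neural miRNA, 12.2-fold on 3 and 77 reads (4.02 to 60.5), and miR-7 3.62-fold (2.85 to 4.65). miR-1 rose 6.93-fold (6.74 to 7.12), from 12149 to 84171 miRNA RPM. miR-2008, an echinoderm miRNA, rose 8.48-fold on 12 and 214 reads (4.76 to 16.7). miR-29 was 4.19-fold lower in gastrula (3.78 to 4.65). Of its 2 forms, AAGCACCAGTTGAAATCAGAGCAA made up 95.2% of miR-29 reads in blastula and 70.3% in gastrula, and TAGCACCATGAGAAAGCAGTAT 4.75% and 29.7%. The former went from 1042 to 386 reads and the latter from 52 to 163, out of 463419 and 974133 miRNA reads. The lower level of miR-29 was therefore that of the former alone, and the latter rose as a part of the miRNA pool.

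Of 26 measured miRNAs 9 were higher in gastrula, 1 lower and 16 neither. In the neural list 4 of 4 were higher, miR-7, miR-9, miR-124 and miR-219 (2.35-fold), and the median log2 ratio of 2.73 stood at the 95.5th percentile of random lists. miR-96 of the sensory list was higher (2.24-fold), and miR-1 was the measured member of the muscle list. In the epithelial list miR-29 was lower and 3 were neither, and its median log2 ratio of -0.62 stood at the 0.920th percentile. The list shared with protostomes had 1 of 6 higher, miR-242 (3.17-fold, 49.8th percentile). The echinoderm list had 2 of 9 higher, miR-2007 (2.60-fold) and miR-2008 (38.6th percentile), and in the let-7 complex let-7 had a ratio of 0.571 (0.411 to 0.796), which on the RPM scale of all reads lay above 1. Of the 4 miRNAs of the study miR-1 was higher, with a median at the 9.51th percentile.

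miR-124, miR-9, miR-2008, miR-1 and miR-7 were called higher, and miR-29, with its forms summed, lower, on each scale run. On the RPM scale of all reads each log2 ratio rises by 0.91, with 16 miRNAs higher and 1 lower, and miR-31, miR-2012, miR-200, miR-2004, miR-2010, miR-2013 and let-7 turned to higher values without a call. With median-of-ratios factors miR-219, miR-242, miR-2007 and miR-96 were not called. With those factors each log2 ratio falls by 0.70, with 5 higher and 6 lower. TMM factors gave 9 higher and 1 lower.

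Between gastrula and pluteus, the feeding larva, few miRNAs changed. miR-137, a neuronal miRNA, rose 2.39-fold on 23 and 51 reads (1.43 to 4.09), and miR-2011 rose 2.15-fold (2.04 to 2.26). let-7 was 2.52-fold lower in pluteus on 84 and 31 reads (1.65 to 3.93), miR-9 2.47-fold lower on 77 and 29 reads (1.59 to 3.92), and miR-96 2.27-fold lower (2.01 to 2.57). miR-219 had a ratio of 0.540 (0.525 to 0.555) and miR-2001 of 0.526 (0.499 to 0.555), just inside the limits. miR-1 had a ratio of 1.14 (1.13 to 1.15), miR-31 of 1.02 (1.02 to 1.02), miR-184 of 1.70 (1.67 to 1.73) and miR-124 of 1.19 (1.03 to 1.36).

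Of 27 measured miRNAs 2 were higher in pluteus, 3 lower and 22 neither. In the neural list miR-137 was higher, miR-9 lower and 3 neither (75.9th percentile), and miR-96 of the sensory list and let-7 of the let-7 complex were lower. The echinoderm list had 1 of 9 higher, miR-2011 (31.6th percentile). The epithelial list had 0 of 4 outside the limits (72.5th percentile), as had the 6 measured members shared with protostomes (70.7th), miR-1 of the muscle list and the 4 miRNAs of the study (65.7th). On the RPM scale of all reads each log2 ratio falls by 0.20, and 1 miRNA was higher, miR-137, and 6 lower, which added miR-34 (2.03-fold), miR-219 (2.12-fold) and miR-2001 (2.18-fold), while miR-1, miR-31 and miR-200 turned to ratios below 1 without a call. TMM and median-of-ratios factors each gave 2 higher and 3 lower.

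The 3′ ends of miRNAs also differed between stages. For the first form of each miRNA, the share of its reads that carried 1 to 4 extra A after its commonest 3′ end was taken. Over the 10 miRNAs with at least 100 reads in every library the median share was 7.27% in ovary, 18.0% in egg, 21.2% in 32-cell, 5.49% in blastula, 1.84% in gastrula and 1.32% in pluteus. In miR-71 the share was 31% in egg (30.4 to 31.6), 33.0% in 32-cell (31.4 to 34.7), 7.50% in blastula (6.38 to 8.76) and 1.64% in gastrula (1.31 to 2.03). In miR-1 it was 13% in egg (12.1 to 13.9) and 0.676% in gastrula (0.621 to 0.734), and in miR-31 36.3% (36.1 to 36.6) and 7.88% (7.81 to 7.95). In miR-2007 it was 46.3% in egg (44.6 to 48.0) and 42.0% in gastrula (40.9 to 43.1). The sequence listed for miR-2007 ends 1 A further than its commonest 3′ end here, so its first extra A is part of the listed miRNA. With more than 1 extra A its share was 11.7% in egg and 0.727% in gastrula. In miR-29 the end taken as commonest closes in AA at 24 nt. That length led in egg (71.5% of reads), but 22 nt led in gastrula (40.7%). Any A added to the shorter end of miR-29 was therefore not counted as extra. The share was higher in egg than in gastrula in 14 of the 14 miRNAs measured in both, higher in egg than in ovary in 17 of 18, and higher in 32-cell than in blastula in 10 of 10. With miRNAs of 30 or more reads these counts were 17 of 20, 18 of 21 and 13 of 15. The median share with extra U was 0.906% in egg, 0.423% in 32-cell and 0.610% in gastrula. With the reads of the 10 miRNAs pooled, the share with extra U was 1.59%, 1.47% and 12.5%. In miR-31, the most abundant miRNA in gastrula, it was 21.1% there. Without a genome an A that the gene itself encodes was counted as extra. This measure was defined after the data were seen.

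**Figure D3:**
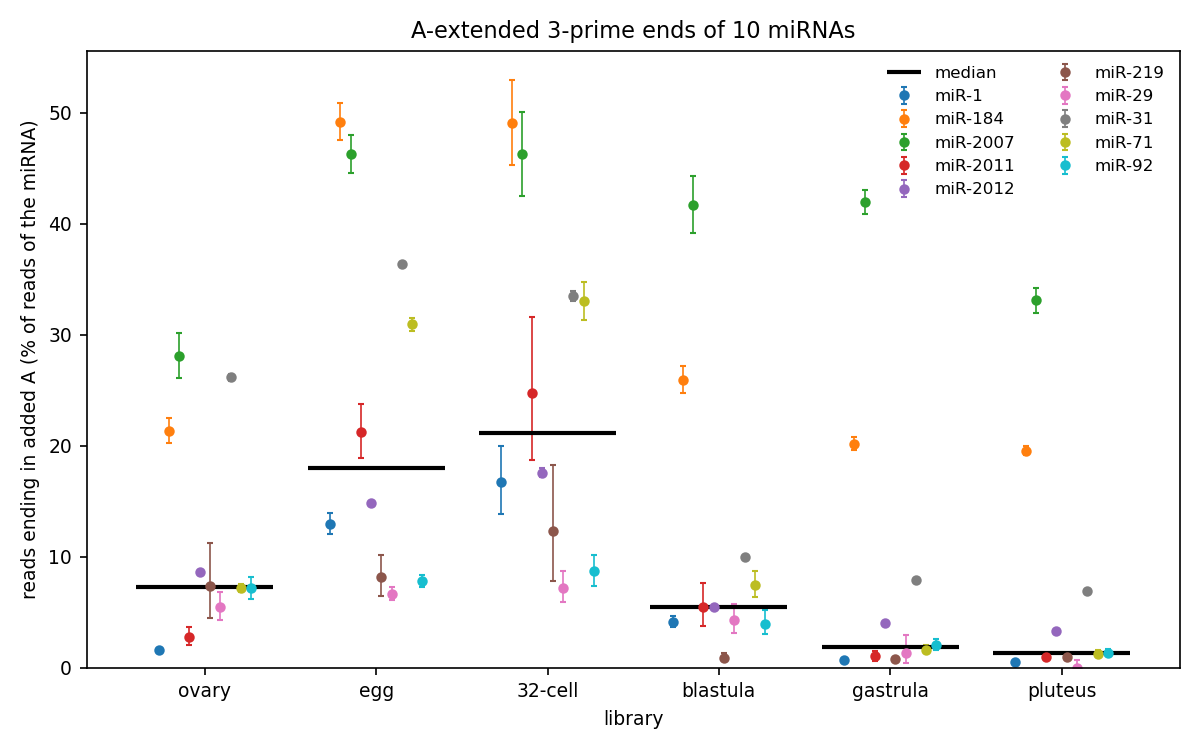
Share of reads with 1 to 4 extra A at the 3′ end (vertical axis, % of the reads of the first form of a miRNA) for 10 miRNAs in the 6 libraries (horizontal axis), with exact 95% counting intervals as bars and the median as a black line. The medians are 18.0% in egg and 21.2% in 32-cell and 1.84% in gastrula.

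Some listed miRNA sequences were not found. Those of miR-133, miR-182, miR-183 and miR-193 had 0 reads in each library, also with a start shifted by up to 1 nt. The largest library, pluteus, then allows up to 0.342 RPM of such a sequence. No form with mismatches passed the search for them either. A miRNA that differs more from the listed sequence, or by an inserted or lost base, would be missed. These counts therefore do not show that the miRNAs themselves are absent. The 11 control miRNAs of human, fly and plant summed to 1 read in the 6 libraries. Outside miRNAs, the 3 most abundant sequences of each library held sequence of the sequencing adapters in 14 of 18 cases, with or without an insert, and an N in 4.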

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

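The tests of breakdown products, of the size range in the egg library and of vertebrate RNA were chosen after the results they bear on were seen. The predictions of the other 3 tests were recorded as written before those tests, but after the patterns they explain were seen. None of these tests was planned before the data were examined. The size range test in egg replaced an earlier test on extra U, whose medians pointed both ways against gastrula (0.906% in egg, 0.423% in 32-cell and 0.610% in gastrula), and a test on the ratio of extra A to extra U, which was dropped. Signals outside the listed miRNAs were noted because they stood far above the level that 0 reads allow.

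Among sequences of 20 to 24 nt that belong to no listed miRNA, AGATGTACCGTGCGATTCAGACTG was the most abundant by mean level, with 2477 RPM in egg. TAGTACTGGCATGGACATTG, which begins and ends like miR-2012 and is 2 nt shorter, reached 554 RPM in gastrula. AGAACTGTGTACGGACATCAGT reached 1230 RPM in gastrula, and 99.4% of the reads starting within 2 nt of it started at the same base. GGGAGCATCTCTCGGTCTATGCTG reached 1969 RPM in ovary. AGGACGGTGGCCATGGAAGTCGG reached 616 RPM in pluteus, with 64.7% of neighbouring reads starting at the same base, where the listed miRNAs checked had between 96.7% and 99.8%. Reads of 32 to 36 nt that begin with a miRNA were 13.7% of miRNA reads of any length in ovary. Reads holding library adapter were 15.4% of the egg library.

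The 32-cell library had few reads of miRNA size, 3.82% at 20 to 24 nt against 21.5% in egg and 11.5% in blastula. Per read of 25 to 31 nt, miRNA reads were 21.6 times as frequent in egg, so they were also low in 32-cell against reads of piRNA size. This ratio is formed from shares already seen, so it is no separate test of whether there were fewer breakdown products. Fewer breakdown products stay open for the rest of the class too. Without miRNA reads it still went from 12.8% in egg to 2.79%, and rRNA fragments from 1327 to 124 RPM. A gel piece cut toward longer RNA would lower short rRNA fragments too, and their ratio of 20 to 24 nt to 25 to 31 nt reads was 0.628 of the lower of the egg and blastula ratios. This lies between the bounds recorded before this test, though after the pattern was seen (at or below 0.5 as a cause, at or above 0.8 as none). Ovary (2.59) and pluteus (2.85) had rRNA ratios near that of 32-cell (2.19), yet 9.13 and 25.7 miRNA reads per 100 reads of 25 to 31 nt against 1.69, which a shifted size range alone would not give if rRNA breaks down alike at each stage. That condition was not tested, so a shifted size range and a difference of the stage itself cannot be told apart. Reads of piRNA size also ran longer in 32-cell, with 1.61 reads of 29 nt per 27 nt read against 0.545 in egg and 0.999 in blastula. A shifted size range would move this number the same way, and its cause was not tested.

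Extra A at the 3′ ends of miRNAs was common in egg, with a median of 18.0% against 1.84% in gastrula. The median is over the same 10 miRNAs in each library, so the mix of miRNAs does not enter it. Addition of 1 A to all ends during library making is argued against by rRNA fragments. Their share with a last A absent from the segment in egg was 0.178 times that in gastrula, on 7 and 52 reads. That check counts 1 added A and is mostly blind to longer tails. In miRNAs the median share with more than 1 extra A was 7.71% in egg, so addition of longer tails stays open. A size range shifted to longer RNA would lower the rRNA ratio of short to long reads, which in egg was 1.06 times that in gastrula (0.949 to 1.18). This argues against such a shift in egg only if rRNA breaks down alike at both stages, which was not tested. The shift stays open for 32-cell, whose median share was 21.2% and whose rRNA ratio was 2.19 against 5.74 in gastrula. As a hypothesis, adenylation of maternal miRNAs may differ between stages, which was not tested here and would need the added A matched to a genome and replicate libraries; a difference between the animals used stays open too.

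let-7 came in 2 forms that differ by G15A, counted from the 5′ end, and the rarer form made up 22.9% of let-7 reads over the 6 libraries. Sequencing error is argued against, since this share is 19.5 times the highest single-base variant share found in 6 other abundant miRNAs. These 6 were taken from miRNAs with a single form here, which left out miR-92. A miRNA with another form at 5% or more of the first therefore could not be among them, which limits this comparison. RNA from a vertebrate is argued against by the 6 human control miRNAs, whose 0 reads allow at most 0.0351% of the let-7 reads. A second let-7 gene, an allele carried by some animals and editing of the RNA stay open and were not tested.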

How the results depend on the processing

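The alternatives with any read length, without the 3 later miRNAs, with the egg library in place of the 32-cell library, for A at position 10, and for 3′ ends were chosen after the data were seen, and the others before. Values are in the order ovary, egg, 32-cell, blastula, gastrula and pluteus unless libraries are named. No paired analysis was possible because each stage had 1 library. A denominator of reads matching the genome was not run, since no genome was at hand.

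The share of miRNA reads moved beyond its counting interval under each alternative, except in 32-cell without the 3 later miRNAs, and the 32-cell library had the lowest share under each. With full mature sequences it was 1.94, 3.71, 0.329, 3.71, 7.36 and 6.23%, as fewer reads qualify. With a match over 16 nt and a start shifted by up to 1 nt it was 3.83, 10.9, 1.19, 6.33, 11.9 and 10.4%. Out of reads of 18 to 31 nt it was 6.59, 19.8, 1.59, 8.80, 18.2 and 16.4%. With reads of any length it was 4.37, 12, 1.29, 7.12, 13.4 and 11.8%. Without the 3 later miRNAs it was 3.74, 10.8, 6.24, 11.7 and 10.2% in ovary, egg, blastula, gastrula and pluteus.

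Over distinct sequences the 20 to 24 nt class held 8.25, 10.9, 3.52, 5.29, 7.93 and 8.07% and the 25 to 31 nt class 32.4, 26.5, 55.2, 48.4, 37.7 and 34.4%. Without miRNA reads the classes held 10.1, 12.8, 2.79, 5.75, 10.2 and 11.2%, and 42.7, 32.6, 70.4, 62.5, 48.1 and 44.7%. Classes of 21 to 23 nt and 26 to 30 nt held 9.11, 15.9, 2.51, 9.28, 17.3 and 16.4%, and 37.8, 25.7, 68.0, 56.6, 39.9 and 37.4%, as narrower limits take fewer reads. The 32-cell library had the lowest short share and the highest long share under each of these alternatives. The share with a 5′ U was 75.9, 78.4, 79.3, 76.8, 74.7 and 71.5% over distinct sequences and 82.3, 84.5, 84.9, 82.9, 80.7 and 77.3% at 26 to 30 nt. The share with A at position 10 was 46.3, 47.9, 43.4, 49.8, 50.7 and 48.1% over distinct sequences and 43.3, 44.0, 42.9, 51.5, 53.5 and 51.6% at 26 to 30 nt. For both base shares the cause was not tested.

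The numbers of called miRNAs depended most on the scale, because a scale adds the same amount to each log2 ratio of a comparison. On the RPM scale of all reads 12 were higher and 6 lower in egg than in ovary, 23 lower in 32-cell than in egg, 15 higher and 2 lower in blastula than in 32-cell, 16 higher in gastrula than in blastula, and 1 higher and 6 lower in pluteus than in gastrula. With TMM factors 1 was higher in egg than in ovary. With median-of-ratios factors 8 were higher in egg than in ovary, 3 lower in 32-cell than in egg, and 5 higher and 6 lower in gastrula than in blastula. With no minimum of reads 3 were lower in gastrula than in blastula, as more miRNAs were tested. With a minimum of 100 reads 1 was higher and 1 lower in pluteus than in gastrula, as fewer were tested. With full mature sequences 0 were lower in 32-cell than in egg and 2 in gastrula than in blastula, and the cause was not tested. With any read length 2 were lower in 32-cell than in egg and 1 higher in pluteus than in gastrula, and the cause was not tested. Without the 3 later miRNAs 1 was higher in pluteus than in gastrula, since miR-2011 is among the 3. With the egg library in place of the 32-cell library 9 were higher and 13 lower in blastula, each within 1.5 times the count with 32-cell.

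The ratios followed here are the 30 of the up to 5 highest and 5 lowest called miRNAs of each comparison, and none of these changed direction in any alternative run on them. Outside these 30, called ratios did turn to the other side when scaled to all reads: miR-184 and miR-2011 (ovary against egg), and miR-92, miR-200 and miR-2007 (32-cell to blastula). With median-of-ratios factors and with no minimum of reads 30 stayed called. With TMM factors 28 did, without miR-96 and miR-219 (ovary against egg), and with any read length 29, without miR-137 (gastrula to pluteus). Scaled to all reads 26 did, without let-7, miR-71 and miR-2004 (32-cell to blastula) and miR-2011 (gastrula to pluteus). With full mature sequences 26 stayed called, and miR-219 (ovary against egg) and miR-252b (egg to 32-cell) did not. With a minimum of 100 reads 22 had a value, each still called, and without the 3 later miRNAs 28. Depth limits the rarest: miR-2001 and miR-252a rest on 1 read each in 32-cell.

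The median share of reads with extra A was 8.50, 29.5, 32.2, 8.73, 3.45 and 2.07% with a minimum of 30 reads. With the reads of the 10 miRNAs of the main measure pooled, the share was 14.1, 25, 26.5, 8.85, 6.58 and 5.94%. Under both, egg and 32-cell had the highest values, and the cause of the shift was not tested.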

Other observations

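No test is reported in this part, and the sequences named were chosen after their values were seen.

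Some unlisted sequences differed widely in level between libraries. TGAGTTGTCCCACAAAGAACAC, with 99.7% of neighbouring reads starting at the same base, stood at 7.17 RPM in ovary, 28.8 in egg, 2.15 in 32-cell, 42.5 in blastula, 224 in gastrula and 178 in pluteus. AATGACCTGAACAGGAGACTCCAG had 3 reads in ovary and 1651 in egg, or 0.430 and 407 RPM, and stood at 123 RPM in 32-cell, 112 in blastula, 173 in gastrula and 208 in pluteus. TCGTTTCCCGGACAAGCCCCCA, which ends in CCA as tRNA fragments do, had 2 reads in egg (0.493 RPM), and stood at 41.9 RPM in ovary, 39.3 in 32-cell, 382 in blastula, 434 in gastrula and 101 in pluteus. These sequences were matched to no gene.

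Fragments of 6 conserved rRNA segments made up 1362 RPM in ovary, 1327 in egg, 124 in 32-cell, 347 in blastula, 1007 in gastrula and 1831 in pluteus. The 3 forms of miR-92 shifted in proportion: TATTGCACTCGTCCCGGCCAGT was 54.9% of miR-92 reads in egg and 27.8% in blastula, and TATTGCACTTGTCCCGGCCTAC was 32.3% and 52.6%. In miR-31 the share of reads with extra U was 3.32% in egg, 20.2% in blastula and 21.1% in gastrula, and this U was not checked against a genome.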
